A study of Mus musculus with 6 samples.

How the data were processed

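RNA-seq libraries from the gastrocnemius muscle of 6 mice aged 3 months were compared: 3 homozygous Dysf mutants of the BLAJ line and 3 C57BL/6 controls, each animal being an independent replicate per the labels' protocols. From 800 ng of RNA, with an integrity number of 7.0 or more, the submitters made poly(A)-selected directional libraries, sequenced as paired 61 bp reads, per the labels' protocols. The 3 controls and mutant replicate 3 were male, and mutant replicates 1 and 2 were female, so sex is unevenly spread over the groups.

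The authors deposited raw read-pair counts per gene, as a matrix of all 6 libraries and as 1 file per library holding an unstranded count and a count for each strand. The submitters' processing notes name FastQC 0.12.1, MultiQC 1.28, STAR 2.7.11b, R 4.5.2, DESeq2 1.50.2 and the build GRCm39, and the annotation release is not given in the sources used here. The deposited count matrix was equal to the unstranded column in every one of 57010 genes, although the library was directional. Unstranded counting leaves read pairs in the overlap of genes on opposite strands unassigned and cannot separate antisense transcription from the gene itself. In these libraries 6.93% to 7.49% of read pairs were ambiguous between genes in the unstranded count and 1.23% to 1.44% in the strand-matched count. Of the reads given to a strand, 6.60% to 7.20% fell on the strand opposite to the gene. The entries for unmapped, multimapping, featureless and ambiguous read pairs name no gene, made up 18.5% to 22.3% of all pairs, and were kept out of library sizes and tests. Because multimapping pairs were not counted, near-identical gene copies keep only the reads that differ between them.

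The authors also deposited a results table with log2 fold changes, standard errors, Wald statistics as scores, p-values and the mean normalized signal per gene, from DESeq2 per the file headers and the submitters' processing notes. Its model formula is not given in the sources used here. It was used only to count overlaps with the calls made here.

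Library totals in the deposited count matrix ran from 35042245 to 43733641 read pairs. At this depth 3 counts in 1 library correspond to 0.068 to 0.0827 CPM (counts scaled to library size), and such limits cover counting error only. No pair of libraries agreed within sampling noise, the closest having a chi-square of 54.6 per degree of freedom over genes.

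The main test was edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM normalization, filterByExpr at its default minimum count of 10, a robust quasi-likelihood F-test of mutant against control with no covariate, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. CPM values use TMM-scaled library sizes. Means are given with the SD over 3 animals, and log2 fold changes (mutant minus control) with their standard error (SE). The 39 gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, and were adjusted over the lists. Each list needed at least 5 tested members. The deposited data carry gene IDs only. Symbols matched 52029 of the 57010 IDs and 15338 of the 15589 tested. Biotypes and neighbouring genes came from GENCODE M21, which is built on GRCm38, so no coordinates are given. Parent genes of pseudogenes were the best blastn 2.17.0 match among protein-coding transcripts of that annotation. Plots were drawn with matplotlib 3.10.9.

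The groups, the test, the gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took Dysf, the 12 called genes with the highest and the 12 with the lowest fold change among those with a mean of at least 1 CPM, an established symbol and no overlap between the groups, up to 4 members per list with the smallest p, sex-linked and substrain marker genes, and called genes within 20 Mb of Dysf. Some genes it took are not reported here. Alternatives were other normalizations (RLE, upper quartile), DESeq2 1.42.0, limma-voom, other filters, sex as a covariate, the replicate number as a block, males only, each library left out, no X or Y genes, strand-matched counts and other thresholds. DESeq2 with sex as a covariate, a test without pseudogenes and DESeq2 on strand-matched counts were chosen after seeing the data.

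The procedure was checked on simulated counts for 15589 genes drawn from the real means, library sizes and dispersions of this comparison. Of genes changed by 2-fold, 16.7% of 66 were recovered, against 77.1% of 70 at 4-fold and 89.1% of 64 at 8-fold. Of 143 calls, 14 were genes that had not been changed and 7 belonged to a list of macrophage markers raised 2-fold as a whole. A simulation with no change gave 1 call and 0 called lists by camera. Genes were simulated independently of each other, so the 0 lists cannot show how camera at the preset correlation handles genes that vary together.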

Results

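The series measured the transcriptome of gastrocnemius muscle from 3-month-old BLAJ mice, a C57BL/6 line carrying the Dysf prmd mutation of strain A/J and lacking dysferlin, and from C57BL/6 controls, with 3 animals in each group. Dysferlin is a membrane protein of the muscle fibre that takes part in resealing the damaged sarcolemma, and its loss causes limb-girdle muscular dystrophy. The deposited count matrix held 40367595, 43733641 and 40990024 read pairs in control replicates 1, 2 and 3, and 36920716, 35042245 and 40230648 in mutant replicates 1, 2 and 3. The mean Pearson correlation of libraries was 0.964 between groups, 0.964 within controls and 0.977 within mutants, so the groups were no further apart than the controls were from each other. The sex-linked genes followed the labels. Xist, expressed from the inactive X, stood at 44.6 and 69.7 CPM in the female mutants and at most 0.153 CPM elsewhere, and Ddx3y on the Y chromosome lay between 110 and 133 CPM in the 4 males and at most 0.276 CPM in the females. Control replicate 1 had the highest share of multimapping pairs, 9.78% against 5.83% to 7.52% in the other libraries, and the highest mitochondrial share, 9.75% against 4.28% to 6.96%. It lay at -59.0 on the second principal component against -6.24 to 35.9 for the others. The labels name its animal in another style (x235) than those of control replicates 2 and 3 (black_1 and black_2). The animal names of mutant replicates 1 and 2 begin with D, and that of mutant replicate 3, the male, with B. What the names stand for is not given in the sources used here.

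The comparison sets BLAJ mutants against animals labelled C57BL/6, to ask what the loss of dysferlin changes in young muscle. The controls had Ifi202b at 1.02 to 7.69 CPM and H2-Ea-ps at 2.37 to 3.44 CPM, genes that C57BL/6 mice do not express, and the mutants had 0 and 1 counts over the group. These values go against the strain label of the controls. Nnt, which carries a deletion in C57BL/6J, was low in the controls, at 0.102 to 0.136 CPM, and does not go against the label. With the strain of the controls in doubt, strain and loss of dysferlin are not separated in any difference below. Dysf (ENSMUSG00000033788) fell from 106 ± 36.9 CPM in controls to 16.9 ± 2.96 CPM in mutants (SD, n = 3 each), a log2 fold change of -2.64 (SE 0.28, edgeR adjusted p = 0.0249). The transcript stood at 72.3, 99.8 and 145 CPM in the controls and at 15.8, 14.7 and 20.3 CPM in the mutants, so every mutant library lay below every control and a residual transcript remained. The direction held in all 20 settings tried, with log2 fold changes from -2.86 to -2.35. With sex as a covariate the change was -2.38 (edgeR adjusted p = 0.546). DESeq2 with sex, chosen after seeing the data, gave -2.40 (adjusted p = 9.86e-06). In males only, with 1 mutant, the change was -2.38 and the call was lost. The edgeR adjusted p also rose to 0.0981 without pseudogenes, and to 0.228, 0.178 and 0.0637 without mutant replicates 1, 2 and 3.

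Of 15589 genes tested, 31 were called by edgeR, 2 higher and 29 lower in the mutants. At an unadjusted p below 0.05 there were 1082 genes where 779 would arise by chance. Fscn2, an actin-bundling protein known from the retina and inner ear, fell from 2.44 ± 0.578 to 0.218 ± 0.0975 CPM (log2 -3.46, SE 0.40, edgeR adjusted p = 0.0314). Hmga1b, a near-identical copy of the chromatin gene Hmga1, fell from 7.08 ± 3.67 to 0.112 ± 0.0882 CPM (log2 -5.92, SE 0.64, edgeR adjusted p = 0.0262), with counts that reads of Hmga1 make uncertain. Kazald1, a secreted protein with a Kazal-type domain, rose from 4.05 ± 0.804 to 14.6 ± 2.76 CPM (log2 1.85, SE 0.22, edgeR adjusted p = 0.0384).

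Pseudogenes made up most of the calls. Of 599 pseudogenes tested, 21 were called (20 lower, 1 higher), against 8 of 13591 protein-coding genes, and the Fisher exact test of pseudogenes against the other genes gave an odds ratio of 54.4 (two-sided p = 4.16e-23, genes not being independent). The processed pseudogenes, intronless copies of spliced transcripts, accounted for 18 of these calls, 17 of them lower. The following genes lie outside the naming rule and were chosen after their values were seen. Gm8730, a copy of the ribosomal gene Rplp0, fell from 109 ± 31.0 to 3.08 ± 1.09 CPM, Rps2-ps10 from 103 ± 41.5 to 0.736 ± 0.238 CPM and Rps26-ps1 from 26.7 ± 4.82 to 0.499 ± 0.146 CPM, with edgeR adjusted p = 0.00471, 0.00174 and 0.0017. Gm11702 was the sole pseudogene to rise, from 0.0412 ± 0.016 to 1.74 ± 0.138 CPM (edgeR adjusted p = 0.00497). These counts share near-identical sequence with parent genes and are uncertain for that reason. H2-Ea-ps, which codes for a class II histocompatibility chain in some mouse strains, fell from 2.98 ± 0.55 to 0.00881 ± 0.0153 CPM, and the class I gene H2-Q1 from 1.28 ± 0.121 to 0.00848 ± 0.0147 CPM (edgeR adjusted p = 0.00551 and 0.0149), each with 1 count over the 3 mutants.

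**Figure D1:**
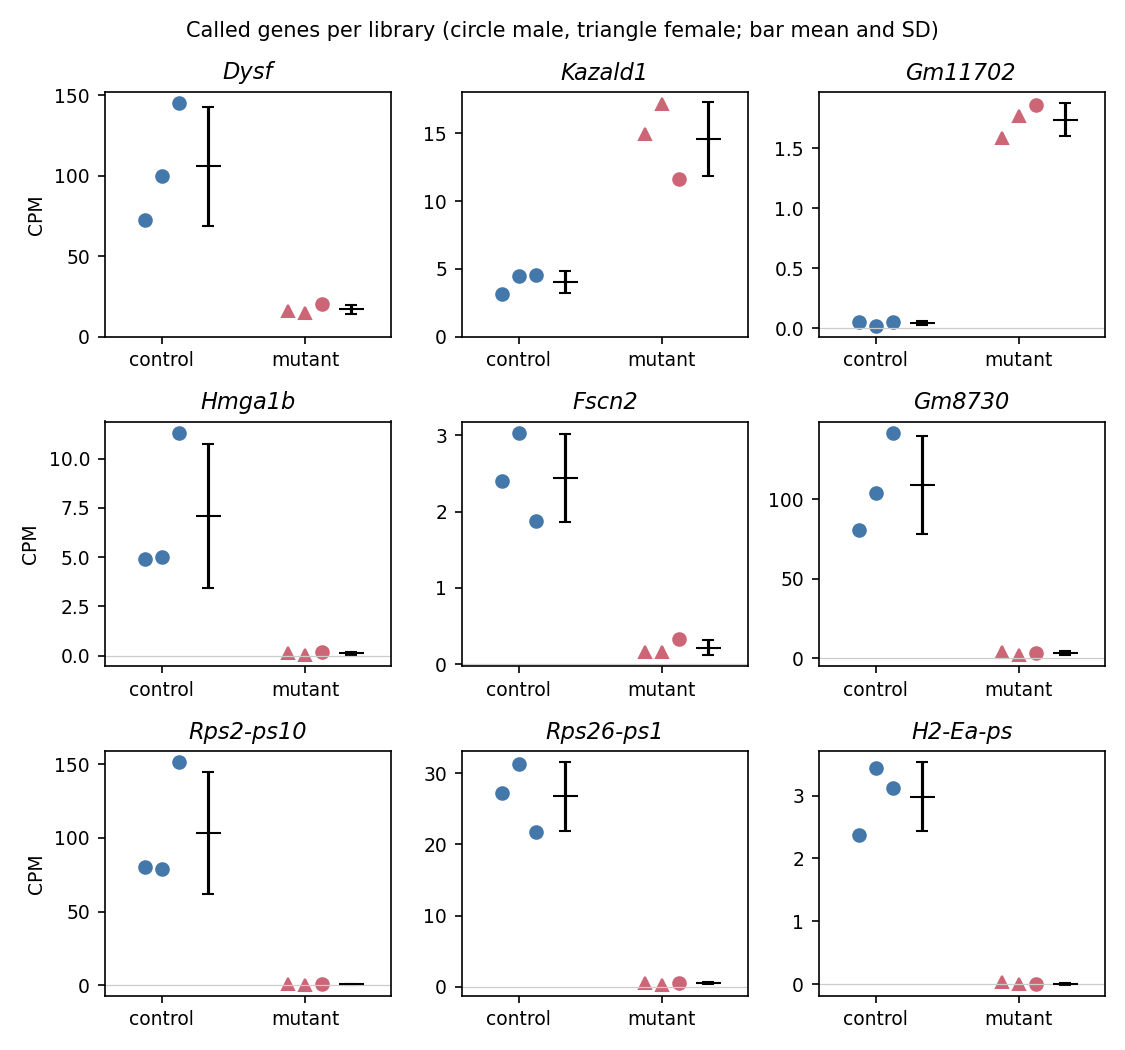
Normalised counts (CPM, linear axes starting at or just below 0) of 9 called genes in each library, circles for males and triangles for females, with the mean and SD over 3 animals beside each group. In every panel the male mutant lies with the female mutants, and the groups do not overlap. The absence of overlap holds for all 31 called genes, which were called with the male mutant included. It therefore follows from the choice of genes and does not speak on sex.

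The count of calls depended on the tool and on single libraries. DESeq2 called 199 genes (55 higher, 144 lower), among them all 31, limma-voom called 21, and edgeR called 0 with sex as a covariate (882 genes at an unadjusted p below 0.05) where DESeq2 with the same covariate, chosen after seeing the data, called 87, of which 28 were shared with the 31. Without pseudogenes edgeR called 0 of 14990 genes (1009 at an unadjusted p below 0.05), and without control replicate 2, mutant replicate 1 or mutant replicate 2 it called 49, 7 and 6. The authors' deposited table listed 205 genes past an adjusted p of 0.05 (55 higher, 150 lower), of which 50 were pseudogenes, and it held all 31 genes called here.

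Of 39 gene lists, 13 were called with the preset correlation (8 higher, 5 lower, limma camera), 0 with an estimated correlation and 0 by fry, whose test asks whether the members move one way on balance. At an unadjusted p below 0.05 the estimated correlation left polyamine and androgen-responsive genes (p = 0.0363) and immediate early genes (p = 0.0135). Among the 10 ways to part the 6 libraries into 3 and 3, 9 gave 13 or more called lists, the real groups included, and the highest count was 23. The number of called lists therefore does not set these groups apart from mixed ones.

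Polyamine and androgen-responsive genes fell together, with 9 of 10 members lower and a median log2 fold change of -1.15 (camera adjusted p = 1.49e-08; adjusted p = 0.708 with an estimated correlation). Adjusted over the list alone, 6 members were lower, against 0 over all genes. Control replicate 2 lay nearest to the mutants in each gene named here. Odc1, the rate-limiting enzyme of polyamine synthesis, stood at 366, 141 and 239 CPM in control replicates 1, 2 and 3 and 76.3 ± 9.05 CPM in mutants. Smox, the spermine oxidase, stood at 618, 179 and 777 CPM in the controls and 155 ± 21.0 CPM in mutants (at most 174 CPM), and Amd2, an S-adenosylmethionine decarboxylase gene with the close copy Amd1, at 30.3, 3.53 and 33.6 CPM and 1.47 ± 0.577 CPM. The controls were all male and mutants 1 and 2 female, and Odc1 stood at 83.3 CPM in the male mutant and 66.1 and 79.6 CPM in the females.

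Immune cell markers moved in different directions. Neutrophil markers fell, all 8 being lower, with a median of -1.57 (camera adjusted p = 1.03e-07; adjusted p = 0.891 with an estimated correlation). Cxcr2, Csf3r and Mmp8 passed when adjusted over the list alone, against 0 members over all genes. The receptor gene Csf3r stood at 5.12 CPM in control replicate 1, 1.90 and 2.29 CPM in the other controls, and 1.11 ± 0.231 CPM in mutants, and without control replicate 1 the list median was -0.99. Macrophage markers rose, with 22 of 28 higher and a median of 0.32 (camera adjusted p = 0.00258; adjusted p = 0.924 with an estimated correlation), and no member passed when adjusted over the list alone. The lysozyme gene Lyz2 stood at 103, 58.7 and 53.3 CPM in the mutants and 47.3 ± 7.37 CPM in controls. Without mutant replicate 1 the macrophage median was -0.00182 (adjusted p = 0.36). The macrophage median was 0.58 without control replicate 3. The call was also lost without control replicates 1 and 2 (medians 0.29 and 0.18, adjusted p = 0.0526 and 0.103), with sex as a covariate (median 0.13, adjusted p = 0.232) and in males only (median 0.13, adjusted p = 0.187). Genes of MHC class II presentation rose (median 0.76, camera adjusted p = 0.00681; adjusted p = 0.924 with an estimated correlation), with H2-Aa at 42.0, 25.1 and 13.7 CPM in the mutants and 14.7 ± 2.90 CPM in controls. The class II median became -0.33 in males only and 0.29 without mutant replicate 1. The call was lost there and without control replicates 1 and 2 (adjusted p = 0.112, 0.36, 0.106 and 0.0517). Interferon-response genes were not called, with 20 of 25 lower. They were called in 2 of 20 settings and in opposite directions, higher without control replicate 1 (median 0.41, adjusted p = 0.000193) and lower without control replicate 2 (median -0.38).

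Lipid and metabolic genes were mixed. Adipocyte markers rose, with 13 of 15 higher and a median of 0.82 (camera adjusted p = 2.02e-06; adjusted p = 0.891 with an estimated correlation). The transcription factor Cebpa, at 8.01 ± 0.672 and 14.1 ± 2.51 CPM, passed when adjusted over the list alone, against 0 members over all genes. The hormone gene Adipoq stood at 9.40 ± 4.97 and 20.8 ± 11.1 CPM, and without mutant replicate 2 the list median was 0.48. Genes of fatty acid oxidation rose, 22 of 23 being higher with a median of 0.23 (camera adjusted p = 0.00172; adjusted p = 0.924 with an estimated correlation). The call was lost without control replicate 2 (median 0.13, adjusted p = 0.116), and the median was 0.38 and 0.16 without control replicate 1 and mutant replicate 3. Genes of sterol and fatty acid synthesis fell, 16 of 19 being lower with a median of -0.41 (camera adjusted p = 0.00788; adjusted p = 0.924 with an estimated correlation). The sterol enzyme gene Cyp51 stood at 11.8 ± 1.20 and 8.82 ± 0.671 CPM. The list was at -0.18 (adjusted p = 0.562) without control replicate 2, at -0.33 (adjusted p = 0.101) without mutant replicate 1, at -0.13 (adjusted p = 0.446) with sex as a covariate and at -0.11 (adjusted p = 0.754) in males only.

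Genes of the neuromuscular junction and of denervation fell, 13 of 18 being lower with a median of -0.47 (camera adjusted p = 0.00561; adjusted p = 0.924 with an estimated correlation). Musk, the receptor kinase that organises the junction, stood at 35.2 ± 9.13 CPM in controls and 11.8 ± 2.06 CPM in mutants (log2 -1.58, SE 0.22), with an edgeR adjusted p of 0.07 over all genes and 0.00299 adjusted over the list alone. Control replicate 2 stood apart in members of this list, with the fetal receptor subunit Chrng at 20.1 CPM against at most 0.749 CPM in the other libraries and Myog at 53.4 against at most 14.0 CPM. It also stood apart in Sln of the lists of regenerating fibres and calcium handling, at 678 against at most 14.6 CPM. Without that library the median of the neuromuscular list was 0.09 (adjusted p = 0.882). Its call was also lost without mutant replicate 2 (median -0.42, adjusted p = 0.0534), with sex as a covariate (median -0.31, adjusted p = 0.444) and in males only (median -0.38, adjusted p = 0.355). The median was -0.77 without control replicate 3. The dystrophin-glycoprotein complex fell by 0.13 in its median (camera adjusted p = 0.0305; adjusted p = 0.924 with an estimated correlation). Dtnb (3.52 ± 0.145 and 1.11 ± 0.54 CPM) was among the members that passed when adjusted over the list alone, against 0 over all genes. The call of the dystrophin list was lost without control replicates 2 or 3 and without mutant replicates 1 or 2. The medians there were -0.10, -0.0033, -0.05 and -0.07 (adjusted p = 0.0672, 0.454, 0.291 and 0.14). The median was -0.27 and -0.32 without control replicate 1 and mutant replicate 3.

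Further lists rose with the preset correlation. Red blood cell genes had all 9 members higher (median 0.55, camera adjusted p = 0.000308; adjusted p = 0.899 with an estimated correlation), with haemoglobin Hba-a2 at 39.7 ± 13.8 and 98.7 ± 27.7 CPM. The red blood cell call was lost without control replicate 1 (median 0.25, adjusted p = 0.0519). The median was 0.93 and 0.36 without control replicates 2 and 3. Immediate early genes had 15 of 20 higher (median 0.36, camera adjusted p = 0.000587; adjusted p = 0.527 with an estimated correlation), with the phosphatase gene Dusp1 at 47.1 ± 13.2 and 92.6 ± 10.1 CPM. The call was lost with sex as a covariate (median 0.06, adjusted p = 0.082) and in males only (median 0.06, adjusted p = 0.1). Endothelial markers had 15 of 18 higher (median 0.21, camera adjusted p = 0.00561; adjusted p = 0.924 with an estimated correlation), with Vwf at 31.6 ± 8.39 and 51.6 ± 5.28 CPM. The endothelial call was lost without mutant replicate 3 (median 0.09, adjusted p = 0.205) and without control replicate 2 (median 0.17, adjusted p = 0.0517). The median was 0.35 without mutant replicate 2 and 0.41 with sex as a covariate. Cell cycle genes had 14 of 17 higher (median 0.78, camera adjusted p = 0.00175; adjusted p = 0.924 with an estimated correlation). Cdk1 stood at 1.88 CPM in mutant replicate 3 and at most 0.370 CPM in the other libraries. Without mutant replicate 3 the list median was 0.14 (adjusted p = 0.362). The cell cycle call was also lost with the filter of 1 CPM in 3 libraries (adjusted p = 0.0645) and without control replicate 1 (adjusted p = 0.0519). Its median rose to 1.87 and 1.55 without control replicate 3 and mutant replicate 2, to 1.44 in DESeq2, to 1.51 with sex as a covariate and to 2.66 in males only.

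**Figure D2:**
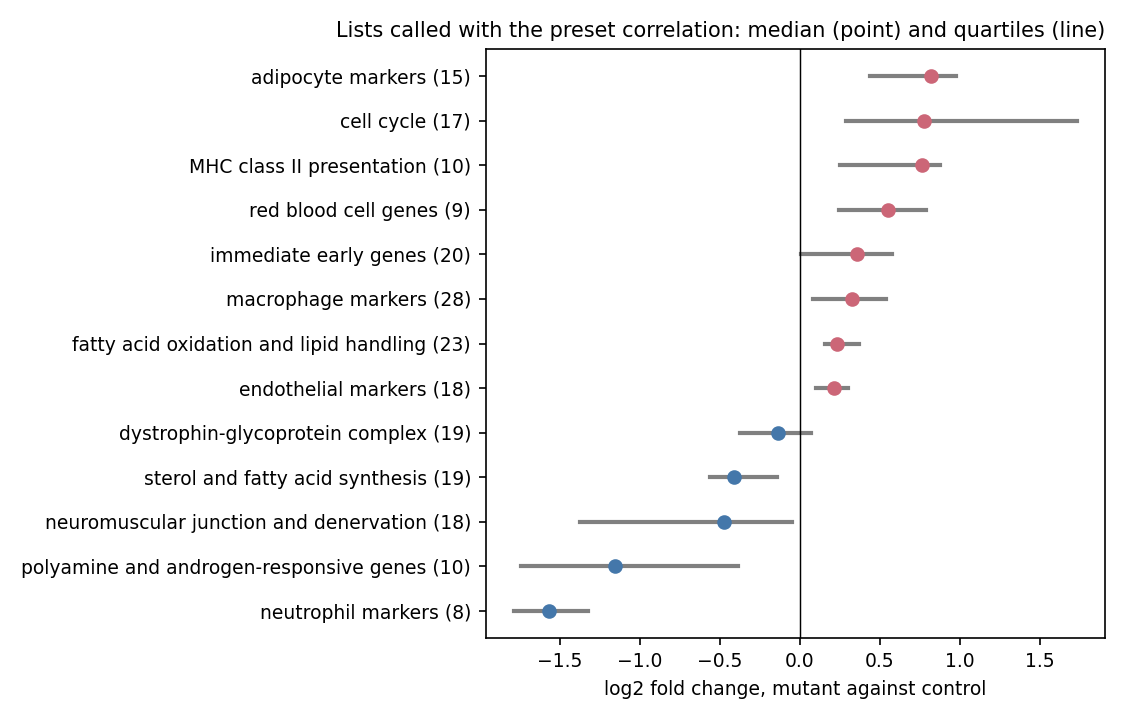
Median log2 fold change (point) and quartiles (line) of the 13 lists called with the preset correlation, with the number of tested members in brackets. Neutrophil markers (median -1.57) and adipocyte markers (median 0.82) lie at the ends, and none of the 13 was called with an estimated correlation. MHC class II genes and the dystrophin complex change sign with sex as a covariate.

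Lists of membrane repair, matrix, regenerating fibres and the clock were not called. Of 26 genes of membrane repair and dysferlin partners, 17 were lower and the median was -0.05 (camera adjusted p = 0.297), with the annexin genes Anxa4 at 21.8 ± 4.77 and 15.5 ± 1.65 CPM and Anxa7 at 116 ± 24.7 and 71.3 ± 22.7 CPM. Genes of the extracellular matrix and fibrosis had 17 of 25 higher (camera adjusted p = 0.297) with Ccn2 at 17.1 ± 5.49 and 33.3 ± 16.6 CPM. The matrix list was called in 6 of 20 settings. Its median ran from -0.67 without mutant replicate 3 to 1.11 with sex as a covariate, and the smallest adjusted p was 8.65e-12. Genes of regenerating fibres had 13 of 19 lower (camera adjusted p = 0.38) and were called in 1 of 20 settings. The circadian clock list was not called as a whole (camera adjusted p = 0.17), and adjusted over the list alone 4 members were higher and 2 lower, against 0 over all genes. The clock output gene Dbp stood at 35.8 ± 5.89 CPM in controls and 72.5 ± 8.52 CPM in mutants, Per3 at 15.3 ± 2.20 and 29.6 ± 3.56 CPM, and Arntl, encoding the activator BMAL1, at 19.0 ± 2.66 and 8.28 ± 2.72 CPM, with no overlap between the groups in any of them.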

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

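DESeq2 with sex as a covariate, the test without pseudogenes and DESeq2 on strand-matched counts were chosen after seeing the data. The counts are given as genes changed, higher and lower in the mutants, against 31, 2 and 29. DESeq2 gave 199, 55 and 144, DESeq2 with sex as a covariate 87, 25 and 62, DESeq2 on strand-matched counts 210, 59 and 151, and edgeR without a filter 79, 18 and 61. limma-voom gave 1 higher gene among 21. edgeR with sex as a covariate, in males only and without pseudogenes gave 0, 0 and 0, with 882, 594 and 1009 genes at an unadjusted p below 0.05. An adjusted p of 0.01 left 9 genes. Leaving out 1 library gave 6 to 49 genes, 0 to 5 of them higher and 6 to 44 lower. With the replicate number as a block, 11 genes were called, 0 higher and 11 lower, all among the 31. With the group means taken out, libraries of the same number had correlations of 0.173, -0.0607 and 0.178. Those of different numbers ran from -0.239 to 0.156. These values are too few to tell whether the numbers pair the animals, and the labels state no pairing. The log2 fold change of Dysf was -2.38 with sex as a covariate, -2.38 in males only and -2.65 without pseudogenes, each with the call lost (edgeR adjusted p = 0.546, 0.998 and 0.0981, the range over all settings being 3.57e-16 to 0.998), and ran from -2.86 to -2.35 with 1 library left out. The fits with sex and in males only rest on 1 male mutant, and the test without pseudogenes holds fewer genes of small p. Lists called numbered 0 with an estimated correlation and 0 by fry, and 9 to 15 in the other settings, with polyamine, neutrophil and adipocyte lists called in all 20 at the preset correlation. Lists whose test reversed with sex as a covariate, in males only and in DESeq2 with sex had medians of 0.016, 0.018 and -0.0016 for the dystrophin complex, -0.32, -0.33 and -0.35 for MHC class II and 0.81, 0.81 and 0.79 for basement membrane. Sex-chromosome genes were at 0.27 in DESeq2 and 0.26 in DESeq2 on strand-matched counts, and T and NK cell markers at -0.47 without a filter. With 1 library left out, interferon-response medians ran from -0.38 to 0.41, called at both ends, and those of the neuromuscular junction from -0.77 to 0.093. The cause of the reversals was not tested. Depth limits genes near 0.07 CPM, the level of 3 counts.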

Other observations

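The tests on sex for the pseudogenes, on genes expressed in 1 group alone, and on splits for the gene lists were chosen only after the results were seen. Genes named here outside the naming rule were chosen after their values were seen.

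Reads on the strand opposite to the annotated gene were tested on their own with edgeR in 5330 genes. Of these genes 5 were called, 0 higher and 5 lower in the mutants (268 at an unadjusted p below 0.05). The unstranded counts include such reads only outside the overlap of genes on opposite strands. Inside an overlap they can come from the other gene. CPM in this paragraph are scaled to the opposite-strand totals and are not on the scale of the other CPM. Opposite-strand reads over the non-coding gene Gm26619 stood at 119 ± 29.4 CPM in controls and 0.555 ± 0.51 CPM in mutants (SD, edgeR adjusted p = 0.000261). Those over Preb, a regulator of secretory vesicle formation, stood at 76.9 ± 21.7 and 9.12 ± 1.41 CPM (edgeR adjusted p = 0.00225). Zfp862-ps was called in the unstranded and in the opposite-strand counts.

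Some genes known to differ between mouse strains separated the groups. Ifi202b, an interferon-inducible gene that C57BL/6 mice do not express, stood at 7.69, 1.02 and 2.62 CPM in the controls. It had 0 counts in the mutants (edgeR adjusted p = 0.321). With the limit of 3 counts set over the mutant group, the mutants lay at least 143-fold below the control mean. Control replicate 1 raises that mean, so the limit is smaller against control replicates 2 and 3. H2-Ea, silent in the class II haplotype of C57BL/6, is listed as H2-Ea-ps, with 2.37, 3.44 and 3.13 CPM in the controls and 1 count over the mutants. Nnt, which carries a deletion in C57BL/6J, stood at 0.102 to 0.136 CPM in the controls and 0.185 to 0.407 CPM in the mutants. Unlike Ifi202b and H2-Ea, its low level in all 6 libraries does not go against the label of the controls.

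A candidate explanation for the 17 processed pseudogenes called lower in the mutants is a genetic background of the control animals that differs from the mutants and from the reference at several loci. The test asked for genes at 1 CPM or more in every library of 1 group and at 0.1 CPM or less in every library of the other, on at least 5 chromosomes. It found 6 such genes on 4 chromosomes, 5 on in the controls and 1 in the mutants. The condition was thus missed, which had been set to count against the explanation. An interval added after the value was seen gives 4 a Poisson 95% upper limit of 10.2. It takes chromosomes as independent counts, which they are not, so it does not undo the missed condition. With 6 such genes the test is weak either way. The other splits of the 6 libraries gave at most 1 such gene. All of these genes but Ifi202b are themselves among the called genes, and AC115117.1 is one of the 17 pseudogenes. The comparison with other splits is thus not separate from the calls to be explained. AC165951.1, H2-Ea-ps and H2-Q1 lie together on chromosome 17. Strain and Dysf genotype cannot be told apart in this design, since every mutant is of 1 line and every control of the other.

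The tables argue against strand as the source of the pseudogene calls, since strand-matched counts gave a median log2 fold change of -4.52 against -4.59, a ratio of 0.986. DESeq2 with sex as a covariate kept 16 of these 17 pseudogenes (median log2 -4.80, SE 0.69) while its calls fell from 199 to 87. The 17 were called with the male mutant among the libraries, which favours their being kept, so this cannot decide on sex. In edgeR their calls ended with sex as a covariate (lowest adjusted p = 0.117), with all 17 at an unadjusted p below 0.05. There the median SE was 0.63 against 0.39 without the covariate, and the median log2 fold change -4.72 against -4.59. Processed pseudogenes called lower between the female mutants and 2 controls, so chosen without the male mutant, had in it 0.605, 0.896 and 1.01 of the females' median change, above the bound of 0.5, which was lowered from 0.8 after the 0.605 was seen. Each of these values rests on 1 male mutant. Together the 3 ratios go against sex as the whole cause only by the lowered bound, and a part played by sex stays open. Reads of the parent genes placed on the copies in the controls may contribute. With Rps26-ps1 left out, 7 of 8 parents whose pseudogene lost at least 5% of the parent's CPM were higher in the mutants (exact binomial two-sided p = 0.0703), and this missed its threshold. The 17 pairs hold 14 distinct parents, and the parent was higher in 14 of the pairs (exact binomial two-sided p = 0.0127). Pairs that share a parent, such as those of Rplp0, are not independent, so this p overstates the evidence. Reads moved between copy and parent would leave their sum unchanged only if they were counted in both groups. Pairs that map to both copy and parent were left out, so the sum can change as well. The sum was higher in the mutants in 13 of the 17 pairs and lower in 4. It changed little for Pcnp (40.2 and 40.4 CPM in controls and mutants) and Rnps1 (39.4 and 41.6 CPM). It rose for Rps2 (432 and 700 CPM). It fell for Psmb5 (60.5 and 50.8 CPM), Osgep (46.1 and 34.8 CPM) and Glo1 (147 and 83.7 CPM), so the sums do not decide.

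Sex may contribute to the changed genes as a whole. Genes called between the female mutants and 2 controls had, in the male mutant against the control left out, a median change of 0.106, 0.152 and 0.199 of that in the females, below the bound of 0.25 set for a sex effect, and genes chosen by their size in the females shrink in any new animal. On autosomal genes, a restriction outside the planned test, the ratios were 0.293, 0.179 and 0.817. DESeq2 with sex as a covariate kept 28 of the 31 genes among its 87 calls. The 31 were called with the male mutant among the libraries, which favours their being kept. In edgeR the median log2 fold change of the 31 was -4.11 without and -4.10 with sex as a covariate. The ratios above rest on the 50, 44 and 22 genes of the fits with the female mutants, not on the 31. The mutation, strain and sex stay open side by side, since strain goes with the mutation and only 1 mutant is male.

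Genes carried along with the mutation from strain A/J would lie near Dysf. Within 20 Mb of it, 0 of 211 tested genes were called, against 29 of 15128 elsewhere. The ratio of shares of 0 lies below 1.5, the bound set beforehand as counting against sequence of the donor strain. An interval added after the value was seen leaves an odds ratio of up to 9.79, so the calls are too few to exclude it. At an unadjusted p below 0.05 the shares were 14 of 211 and 1048 of 15128, a ratio of 0.958. The window leaves out the rest of chromosome 6, which holds Dysf. That chromosome had the most calls of any, 5 of 790 tested genes with Dysf among them, next to 4 of 736 on chromosome 17.

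The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real groups gave 31 genes, the highest other split 9 genes, and 1 of the 10 splits, the real one, reached 31. For lists at the preset correlation the real groups gave 13 and the highest other split 23, and 9 of the 10 splits gave 13 or more.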
